A study of Mus musculus with 2 samples.

How the data were processed

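Total RNA of the left cerebral cortex of 2 female B6CASTF1/J mice (10 days old) was sequenced after reduction of ribosomal RNA, with 300 ng of RNA and ERCC spike-ins per library, per the labels. Both samples form 1 group with n = 2. Whether the females were littermates, or the libraries were prepared together, is not given in the sources used here, so the SD and the dispersion describe these 2 animals only. The group, the gene lists, the gene pairs, the isoform genes, the comparisons of the report, the rule for naming genes and most of the alternatives were chosen before the data were examined. Tests of explanations are in the closing section, which says which of them were chosen after the result was seen.

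Each sample came with 3 tables. Expected counts per gene and per transcript were made by the authors from alignments to the transcriptome of assembly mm10 with annotation M21, per the deposited README files. TPM values in the same tables were scaled by the authors over all rows, including spike-ins, per the file headers. The columns are those of RSEM, but the tool and its version are not given in the sources used here, nor is the level of the credible intervals. The estimated counts and TPM of the alignment-free transcript tables were made by the authors straight from the sequence reads, per the deposited README files, and their columns are those of kallisto; here the tool and version are again not given in the sources used. These values were summed per gene. The reads were quantified against the mm10 reference, so that reads of alleles that differ from it can map less well; no allele was separated here.

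All 55536 gene rows with an Ensembl identifier and all 141862 transcript rows matched GENCODE M21 by versioned identifier, and coordinates, strands, gene types and exon counts were taken from that annotation (mm10, counted from 1). The tables also held 96 ERCC spike-ins, phiX with 0 reads, and 26248 rows named by a number only. Spike-ins took 0.413% of reads in replicate 1 and 0.401% in replicate 2, and the numbered rows 6.88 reads and 1 read; these rows were left out of gene counts and scaling. Genes held 29867112 reads in replicate 1 and 31031340 in replicate 2. A count of 0 allows up to 3 reads at 95% confidence, or 0.16 and 0.147 TPM for a transcript of 1 kb. Counting limits cover counting error only, and standard errors of list medians reflect the spread over member genes. Neither covers differences between animals, and members of a list can vary together.

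Levels are the mean and SD of TPM. A gene was detected at 1 TPM or more in both libraries. A list's level is the median TPM of its members per library. Pair ratios are log2 of TPM + 0.1 over TPM + 0.1 within a library, and a pair was set beyond the replicate spread when both libraries had the same sign and the mean exceeded 2 SD. Shares of transcripts were computed for isoform genes at 10 TPM or more. Agreement is Pearson r and Spearman rho of log2(TPM + 1). Dispersion was estimated with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on expected counts rounded to integers, with TMM factors, filterByExpr and an intercept-only design. Genes differing between the libraries are those at least 2-fold apart in TMM-scaled counts with a mean of 100 expected reads or more, with 0.5 added to each count in the ratio. Folds against a library with under 1 read are given as bounds over 3 reads. For list shifts, the median log2 ratio of members with a mean of 20 reads or more was set against 10000 random lists of the same size matched in 20 bins of expression, for lists with 4 such members or more. No p-value was computed, since 2 animals cannot give an exact two-sided p under 0.5. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and DESeq2 1.42.0 served for its size factors in an alternative.

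Genes were named by a rule. In each list these are its 3 highest members, its lowest member, and members under 1 TPM or over 2-fold apart between libraries. The rule further takes both genes of each pair, the 20 gene rows highest in TPM, the 10 largest and 10 smallest ratios between libraries at a mean of 100 reads or more, the 10 isoform genes highest in TPM with those whose leading transcript differed between libraries or quantifications, and the 10 genes furthest apart between quantifications at 10 TPM or more in either. Some genes that the rule takes are not reported here. Other named genes are said to be chosen after their values were seen.

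The dispersion and ratio steps were tested on simulated data drawn from the real means. With a set coefficient of 7.58% for replicate 2 against replicate 1 over 55536 simulated genes, 7.50% was recovered with no gene changed and 11.1% with 200 changed. The 2-fold limit was passed by 0 of 50 genes changed 1.5-fold, 24 of 50 changed 2-fold, 50 of 50 changed 3-fold, 50 of 50 changed 4-fold and 0 unchanged genes. In simulated lists of 12 genes from 16459, added shifts of 0, 0.25, 0.5 and 1 returned medians of -0.01, 0.23, 0.48 and 0.98. A shift added to every member moves the median by that amount, so these medians are no check of the step. Among random lists they lay at percentiles 34.22, 99.99, 100 and 100. Lists whose members vary together were not simulated.

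Alternatives covered the detection limit, the filter, the pseudocount, the scaling, the unit, the quantification and each replicate alone. Chosen after seeing the data were scaling by spike-in reads, the removal of the trend with GC content and length, the centring of TPM ratios on their median over all genes, a subset of transcripts matched in GC content, a search of genes under 350 bases for words of 31 bases shared with the M21 transcripts of other genes, and the summary values and tolerances by which alternatives were set side by side. The pairing of 3 chromosome 1 pseudogenes with mitochondrial genes rests on order and spacing, which are the same in both places (914 and 1594 bases from the first gene).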

Results

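The data were total RNA sequencing of the left cerebral cortex of 2 female mice at 10 days of age. The labels give the animals as B6CASTF1/J. They name them as separate females and as biological replicates 1 and 2 of a single group. No treated, older or male samples were analysed here, so the design gives no comparison between groups. The questions it leaves are what the cortex of a 10-day-old mouse expressed, how its genes stood to each other within a library, and how far the 2 animals agreed. Each library was made from 300 ng of RNA with ERCC spike-ins, which are synthetic transcripts added at set amounts. The gene tables held 29990965 expected reads for replicate 1 and 31156256 for replicate 2. Values are means of TPM, a length-normalised share of all transcripts, ± SD over 2 animals (n = 2 throughout), and 2 animals cannot give an exact two-sided p under 0.5, so no p-value was computed. At these depths a count of 0 allowed up to 3 reads, which for a transcript of 1 kb is 0.16 TPM in replicate 1 and 0.147 TPM in replicate 2; such limits cover counting error only.

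At 1 TPM or more in both libraries, 14947 genes were detected, 13016 of them protein-coding. These were 59.1% of the 22028 annotated protein-coding genes. Long noncoding RNAs were detected far less often, with 706 of 10155 annotated genes, though this count ranged from 195 at 5 TPM to 1411 at 1 TPM in the alignment-free tables. Replicate 1 alone had 15894 genes at this level and replicate 2 alone had 15337.

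Nuclear protein-coding genes held the largest share of the transcripts, followed by small structural RNAs. Protein-coding genes took 49.7% ± 1.67 of TPM, and the class that holds 7SL and 7SK RNA took 30.97% ± 2.41. Mitochondrial ribosomal RNA followed with 5.10% ± 0.732, pseudogenes with 3.31% ± 0.0952, lincRNA with 3.05% ± 0.232, snRNA with 2.21% ± 0.124 and the 13 mitochondrial protein-coding genes with 2.19% ± 0.171. Much of the lincRNA share was held by Gm26917 (1.58%) and Gm42418 (0.432%). Both are lincRNA rows by annotation only, and the origin of their reads was not tested. The pseudogene share includes Gm28661 (0.593%), Gm10925 (0.47%) and Gm28437 (0.37%). These 3 rows share reads with mitochondrial genes, so that the division between these classes is uncertain. By share of reads, where long transcripts weigh more, nuclear protein-coding genes took 83.1% ± 0.137 and the 7SL and 7SK class 4.08% ± 0.461. In the alignment-free quantification the protein-coding share of TPM was 79.5% ± 0.673, and the 7SL and 7SK class was at 0.00327% ± 0.000914.

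The 20 most abundant gene rows were led by the 7SL genes Rn7s1 (chromosome 12, 69159295 to 69159594) and Rn7s2 (chromosome 12, 69361182 to 69361481), the RNA of the signal recognition particle. Each held 13.3% of all TPM, and the same value in both rows shows that reads of these near-identical copies were divided evenly. Rn7sk, the RNA that restrains the elongation factor P-TEFb, held 4.29%, and the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 held 3.19% and 1.91%. Gm26917 and Gm42418, 2 neighbouring lincRNA rows on chromosome 17 (39843013 to 39846341 and 39846958 to 39848788), held 1.58% and 0.432%. The RNase P and RNase MRP RNAs Rpph1 and Rmrp were at 8687 ± 393 and 2771 ± 345 TPM. The snRNA copies Gm23444 and Gm23472 were each at 2318 ± 222 TPM, again an even division. Among mitochondrial mRNAs, mt-Co1 was at 4735 ± 330, mt-Nd1 at 2755 ± 179, mt-Cytb at 2668 ± 148 and mt-Atp6 at 2183 ± 77.1 TPM. The unprocessed pseudogenes Gm28661, Gm10925 and Gm28437, which lie side by side on chromosome 1 between 24613189 and 24615565, were at 5927 ± 273, 4696 ± 333 and 3702 ± 107 TPM, and values of these rows and of their mitochondrial counterparts are uncertain because they share reads: Gm28661 is a copy of mt-Co2, Gm10925 of mt-Atp6 and Gm28437 of mt-Co3. Malat1, a nuclear noncoding RNA, was at 2510 ± 677 TPM, and Tuba1a, a tubulin of growing neurons, at 2252 ± 87.7 TPM was the highest nuclear protein-coding gene of the alignment-based tables; in the alignment-free tables Actb (3538 TPM), Eef1a1 (3367 TPM) and Gapdh (3192 TPM), chosen after their values were seen, exceeded it (3171 TPM).

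**Figure D1:**
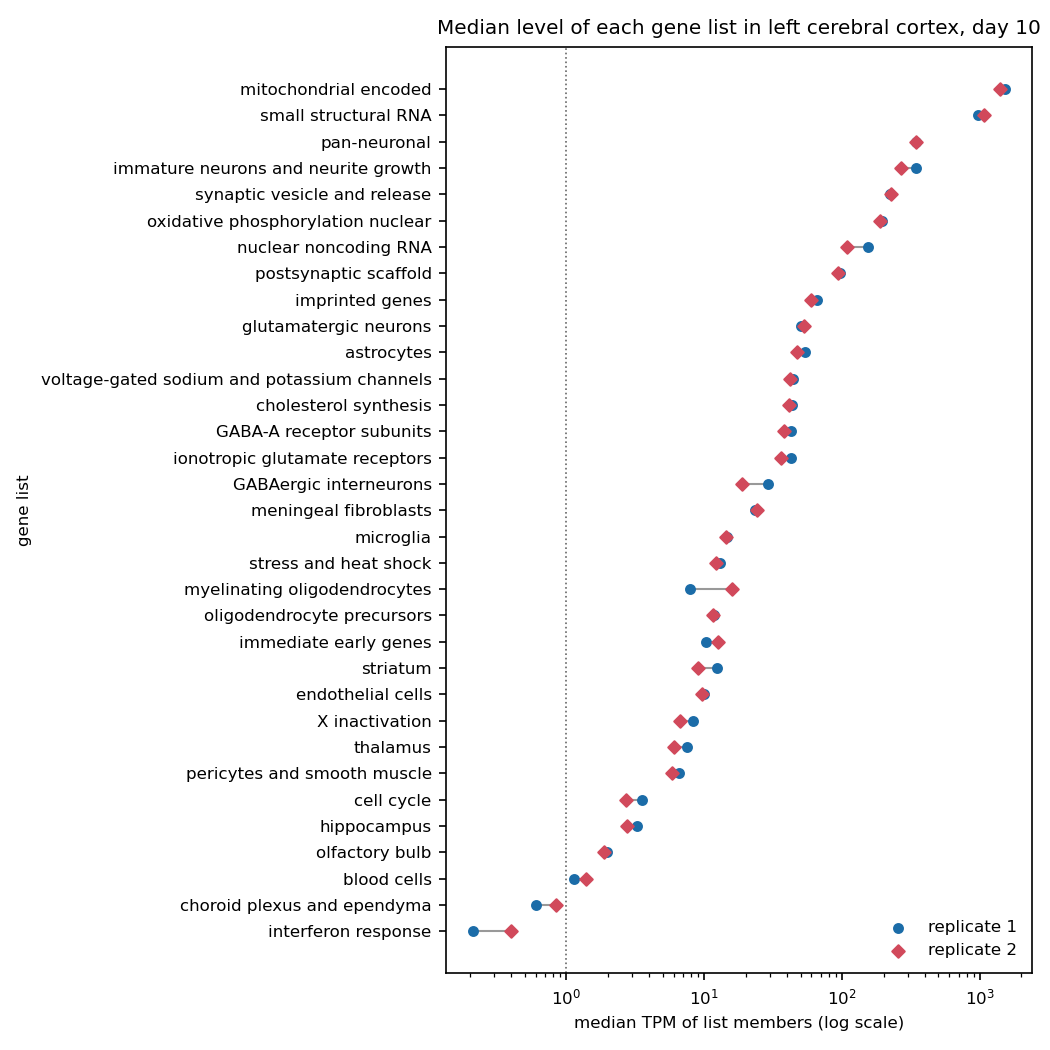
Median TPM of the members of each gene list (log axis) in replicate 1 (circles) and replicate 2 (diamonds), with a dotted line at 1 TPM; the Y-linked list, with a median of 0, is not drawn. The pan-neuronal list lies near 345 TPM in both libraries, and the myelinating oligodendrocyte list has the medians 7.89 and 16.0 TPM.

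The pan-neuronal list was the most abundant of the cell classes. The median of the 12 pan-neuronal genes was 346 ± 1.08 TPM, with Stmn2, a regulator of microtubules in growing axons, at 1048 ± 85.9, Tubb3 at 677 ± 12.4 and Uchl1 at 619 ± 43.3 TPM; the lowest, Elavl4, was at 54.3 ± 5.81 TPM. The glutamatergic list had a median of 51.8 ± 1.64 TPM and all 14 members at 1 TPM or more in both libraries. Its highest members were the calmodulin-binding postsynaptic gene Nrgn (991 ± 147 TPM), the vesicular glutamate transporter Slc17a7 (511 ± 14.4 TPM) and Camk2a (507 ± 24.0 TPM), and its lowest was the deep-layer gene Foxp2 (6.10 ± 0.0566 TPM). The 15 GABAergic interneuron genes had a median of 24.0 ± 7.42 TPM. The neuropeptide genes Cck and Sst led that list with 220 ± 17.8 and 160 ± 3.15 TPM, followed by the GABA-synthesising enzyme Gad1 with 68.8 ± 15.5 TPM, and the serotonin receptor Htr3a was lowest with 1.60 ± 0.191 TPM.

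Among glial and vascular classes, the astrocyte list had a median of 50.5 ± 4.58 TPM, near that of the glutamatergic list, with the glutamate transporters Slc1a2 and Slc1a3 at 660 ± 17.0 and 139 ± 9.07 TPM, the glycolytic enzyme Aldoc at 145 ± 2.16 TPM and the transcription factor Sox9 lowest at 9 ± 0.0566 TPM. Oligodendrocyte precursor genes had a median of 11.7 ± 0.0177 TPM, with Olig1 at 48.0 ± 0.742, Pdgfra at 33.0 ± 4.63, Gpr17 at 30.8 ± 4.25 and Neu4 at 3.63 ± 0.410 TPM. Genes of myelinating oligodendrocytes had a median of 11.9 ± 5.71 TPM, the widest relative spread of any cell class: the myelin protein Mbp was at 135 ± 64.2 TPM, Cnp at 46.7 ± 14.8 TPM, and Ermn and Opalin below 1 TPM (0.635 ± 0.389 and 0.355 ± 0.247). Microglial genes had a median of 14.6 ± 0.138 TPM, with the purinergic receptor P2ry12 (31.005 ± 1.03) and Csf1r (30.015 ± 1.36), with Trem2 lowest (3.45 ± 0.438 TPM). Endothelial genes had a median of 9.81 ± 0.184 TPM, with the tight-junction gene Cldn5 at 42.0 ± 0.0283, Itm2a at 26.0 ± 2.87, Esam at 14.2 ± 0.445 and Emcn at 3.03 ± 0.325 TPM. Pericyte and smooth muscle genes had a median of 6.19 ± 0.537 TPM, with Rgs5 at 48.4 ± 1.67, Vtn at 35.5 ± 1.80, Cspg4 at 10.8 ± 0.460 and Myh11 at 1.43 ± 0.106 TPM. Meningeal fibroblast genes had a median of 23.7 ± 0.636 TPM, with the prostaglandin synthase Ptgds at 512 ± 10.9, Igf2 at 110 ± 2.60, Pdgfra again at 33.0 and Lum at 1.78 ± 0.113 TPM. These are levels of marker transcripts in whole tissue, not shares of cells.

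Genes of synapses, neurite growth and respiration stood among the highest protein-coding genes. The list of immature neurons and neurite growth had a median of 306 ± 56.8 TPM, led by Stmn1 (1024 ± 44.8), Tubb2b (656 ± 61.9) and the growth cone gene Gap43 (547 ± 38.7), with Igfbpl1 lowest (1.56 ± 0.177 TPM). The synaptic vesicle list had a median of 225 ± 3.56 TPM, with Syp at 850 ± 14.6, Snap25 at 592 ± 3.24, Vamp2 at 549 ± 7.51 and the active-zone scaffold Pclo at 51.2 ± 4.43 TPM. Postsynaptic scaffold genes had a median of 95.1 ± 2.31 TPM, with Camk2a highest, then Dlg4 (443 ± 18.6 TPM) and Camk2b (385 ± 9.77 TPM), and Homer2 lowest (33.8 ± 2.20 TPM). Nuclear genes of oxidative phosphorylation had a median of 193 ± 4.43 TPM, with Atp5b at 797 ± 30.2, Cox4i1 at 505 ± 7.54, Atp5a1 at 389 ± 6.39 and Cycs lowest at 24.0 ± 1.26 TPM, though Cycs was at 275 TPM in the alignment-free tables and not lowest there. The 13 mitochondrially encoded mRNAs had a median of 1468 ± 88.6 TPM, and the lowest, mt-Co2 (77.7 ± 18.5 TPM), shares its sequence with the pseudogene Gm28661, which took most of the reads of the pair (67677 and 69096 together, of which mt-Co2 held 1.47% and 1.12%). In the alignment-free tables mt-Co2 was at 1042 TPM.

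Receptors and channels lay below the scaffolds. Ionotropic glutamate receptor genes had a median of 39.2 ± 4.36 TPM, with Gria2 at 203 ± 23.9, Grin1 at 191 ± 0.0919, Grin2b at 160.5 ± 15 and Grin2c at 7.38 ± 0.156 TPM. GABA-A receptor genes had a median of 40.1 ± 3.40 TPM, with Gabrb2 at 79.3 ± 1.86 TPM. Gabra6, a subunit of cerebellar granule cells, had 0 reads in replicate 1 and 6 in replicate 2. Sodium and potassium channel genes had a median of 43.0 ± 1.46 TPM, with Scn2a at 170 ± 11 and the axonal channel Kcna1 at 17.3 ± 0.884 TPM. Genes of cholesterol synthesis, which the growing brain runs by itself, had a median of 42.1 ± 1.45 TPM. Hmgcs1 was highest (319 ± 28.9 TPM), and Fdps was at 84.5 ± 3.75 TPM.

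Activity, stress and division genes were moderate to low. Immediate early genes had a median of 11.5 ± 1.67 TPM, with Homer1 at 72.1 ± 2.18, Egr1 at 43.3 ± 5.71, Egr3 at 34.0 ± 0.834 and Fosb at 1.36 ± 0.403 TPM. The Homer1 level sums all of its transcripts, led by Homer1-203 (366 codons) with 35.7% ± 1.2. The stress list had a median of 12.5 ± 0.608 TPM. It spanned the constitutive chaperone Hspa8 (1095 ± 8.49), Hsp90aa1 (482 ± 41.6) and Hsph1 (122 ± 1.12) down to the inducible Hspa1b (0.880 ± 0.438) and Atf3 (0.420 ± 0.0566 TPM). Cell cycle genes had a median of 3.12 ± 0.608 TPM, with Pcna at 28.4 ± 0.346, Mcm5 at 4.97 ± 0.240, Top2a at 4.87 ± 0.148 and Bub1 at 0.845 ± 0.431 TPM. The interferon list was lowest of the processes, with a median of 0.305 ± 0.134 TPM and 3 of 11 members at 1 TPM or more in both libraries, among them Ifi27 (11.4 ± 3.40) and Ifitm3 (4.45 ± 0.276). Bst2 (1.01 ± 0.764), Ifit3 (0.470 ± 0.382), Irf7 (0.255 ± 0.205), Isg15, Oasl2, Rsad2, Ifit1 and Usp18 lay lower, and none of these 8 had over 25 reads in a library. Imprinted genes had a median of 62.5 ± 4.04 TPM, led by the noncoding Meg3 (1418 ± 294), Snurf (1035 ± 53.5) and Gnas (967 ± 3.48), with Dlk1 at 0.740 ± 0.438 TPM; Snurf, of 216 bases, was at 0 TPM in the alignment-free tables. Nuclear noncoding RNAs had a median of 131 ± 31 TPM, led by Gm26917 (15806 ± 1120), Malat1 and Meg3, with Kcnq1ot1 lowest (2.54 ± 0.742 TPM). Gm26917 is a lincRNA row by annotation only, and the origin of its reads was not tested. The small structural RNA list had a median of 1023 ± 79.2 TPM, with Rnu11 lowest (2.23 ± 1.17 TPM), and a median of 0 TPM in the alignment-free tables.

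Markers of other tissues gave the background for the dissection. Members of these lists can also be expressed in cortex, so their levels do not measure carry-over. Calb2 of the thalamic list, for example, is also in the GABAergic interneuron list. Striatal genes had a median of 10.6 ± 2.35 TPM, with Ppp1r1b at 24.995 ± 6.17, Pde10a at 24.8 ± 6.12 and Six3 at 0.525 ± 0.332 TPM; cortex also expresses several of these. Thalamic genes had a median of 6.73 ± 1.03 TPM, led by Calb2 (24.0 ± 7.42), Slc17a6 (20.95 ± 3.59) and Rora (20.2 ± 0.148), with Synpo2 (0.760 ± 0.0707) and Gbx2 (0.0700 ± 0.0424) under 1 TPM. Hippocampal genes had a median of 3.00 ± 0.368 TPM, with Wfs1 at 37.8 ± 5.91, Calb1 at 35.7 ± 1.22, Zbtb20 at 19.5 ± 1.54 and Spink8 at 0.260 ± 0.226 TPM; Iyd, C1ql2 and Dsp were also below 1 TPM. Olfactory bulb genes had a median of 1.93 ± 0.0813 TPM, with Meis2 at 49.4 ± 7.23, Slc17a6 again, Cdhr1 at 7.59 ± 2.60 and Tbx21 at 0.0300 ± 0.0141 TPM; Th and Eomes were also below 1 TPM. In the choroid plexus and ependyma list, with a median of 0.720 ± 0.170 TPM, Enpp2 (67.0 ± 6), Ttr (6.84 ± 4.04) and Foxj1 (1.59 ± 0.332) were highest and Otx2 lowest (0.180 ± 0.0849 TPM), with Kl, Kcnj13, Ccdc153, Clic6, Folr1 and Tmem212 also below 1 TPM. In the blood list, with a median of 1.26 ± 0.184 TPM, the globins Hbb-bs (261 ± 29.5), Hba-a1 (229 ± 41.0) and Hba-a2 (211 ± 31.2) were highest. Ptprc (0.995 ± 0.191), Slc4a1 (0.230) and Cd3e (2 reads and 0) were below 1 TPM, and the neutrophil genes S100a8 and S100a9 had 0 reads in replicate 1 and 11 and 8 in replicate 2.

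Genes of the sex chromosomes were read as a check of the label, female. Xist (chromosome X, 103460366 to 103483254, minus strand), the RNA that coats the inactive X chromosome, was at 94.6 ± 10.9 TPM. The other members of the X inactivation list, Ftx, Jpx and Tsix, were at 7.62 ± 0.573, 7.43 ± 1.73 and 0.320 ± 0.113 TPM, and the median of the list was 7.52 TPM. Of 7 Y-linked genes, Kdm5d had 3 reads in each library, and Ddx3y, Eif2s3y, Uty, Usp9y, Zfy1 and Sry were at 0 TPM.

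**Figure D2:**
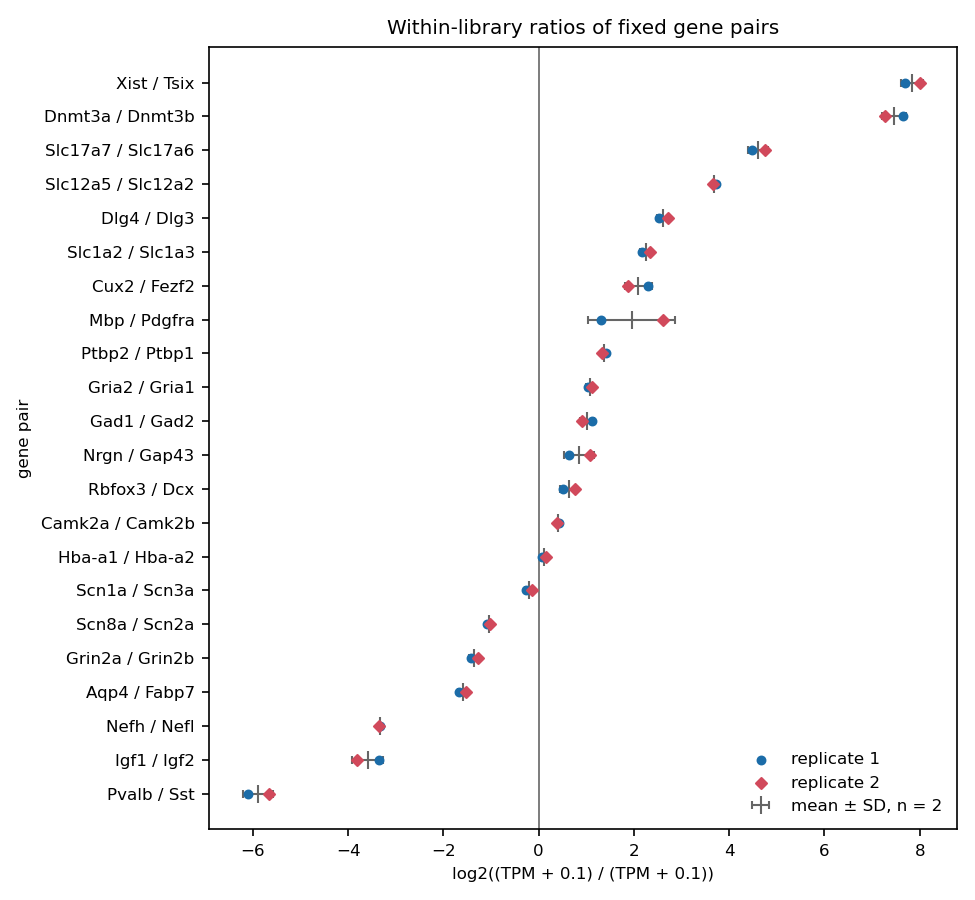
Log2 ratio of TPM (pseudocount 0.1) for 22 of the 24 gene pairs within replicate 1 (circles) and replicate 2 (diamonds), with the mean and SD of both libraries (vertical tick and bar, n = 2). Xist over Tsix is highest at 7.84 and Pvalb over Sst lowest at -5.89; Mbp over Pdgfra has the widest bar.

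Pairs of receptor, transporter, scaffold and channel genes were compared within each library, at 1 age only. The juvenile NMDA receptor subunit Grin2b exceeded the adult subunit Grin2a by 2.54-fold (log2 ratio of Grin2a over Grin2b -1.35, with -1.42 and -1.27 in the libraries). The chloride exporter Slc12a5 (KCC2) exceeded the importer Slc12a2 (NKCC1) by 12.9-fold (164.8 ± 11.3 against 12.7 ± 0.410 TPM). Among scaffolds, Dlg4 (PSD-95) exceeded Dlg3 (SAP102) by 6.11-fold. AMPA receptor subunit Gria2 exceeded Gria1 by 2.10-fold, and Camk2a exceeded Camk2b by 1.32-fold. The sodium channel Scn8a was below Scn2a by 2.08-fold, while Scn1a and Scn3a had a log2 ratio of -0.20, with overlapping credible intervals in replicate 2 (21 to 24.1 and 23.3 to 26.2 TPM).

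Other pairs set cell states and classes side by side. The mature neuronal marker Rbfox3 exceeded the immature marker Dcx by 1.55-fold, and Nrgn exceeded Gap43 by 1.80-fold. Slc17a7 exceeded Slc17a6 by 24.5-fold, and Slc1a2 exceeded Slc1a3 by 4.75-fold. The water channel Aqp4 of mature astrocytes was below Fabp7, a gene of radial glia and immature astrocytes, by 3.01-fold. Mbp exceeded Pdgfra by 3.87-fold, with log2 ratios of 1.31 and 2.60 in the 2 libraries. Pvalb, whose interneurons mature late, was below Sst by 59.3-fold (2.64 ± 0.636 against 160 ± 3.15 TPM). Gad1 exceeded Gad2 by 2.01-fold, Ptbp2 exceeded Ptbp1 by 2.59-fold (log2 ratio 1.37, against 2.26 in the alignment-free tables), and the methyltransferase Dnmt3a exceeded Dnmt3b (0.865 ± 0.205 TPM) by 176-fold on the pseudocount scale, which understates ratios to low genes. Nefh was below Nefl by 10.1-fold and Igf1 below Igf2 by 12.1-fold. The upper-layer gene Cux2 exceeded the deep-layer gene Fezf2 by 4.24-fold. Xist exceeded Tsix by 229-fold, though Tsix overlaps Xist on the opposite strand and its value is uncertain unless counting used the strand. The near-identical globins Hba-a1 and Hba-a2 differed by 1.08-fold (log2 ratio 0.11, against 1.83 in the alignment-free tables) and share reads. In all 24 pairs both libraries had the same sign and the mean exceeded 2 SD, a criterion that 2 values around 0 meet by chance in 21.6% of cases, or 5.2 of 24 pairs. The deposited credible intervals, whose level the files do not give, lay apart in both libraries for 22 pairs, the exceptions being Scn1a with Scn3a and the globins.

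Leading transcripts were stable between animals for the isoform genes. Of 44 genes fixed for isoforms, 43 reached 10 TPM (Bdnf did not), and in all 43 the most abundant transcript of the alignment-based tables was the same in both libraries. The 10 with the highest level were Stmn2, Gnas, Mef2c, Snap25, App, Map2, Ptgds, Dclk1, Camk2b and Ncam1. App-201 (chromosome 16, 84954443 to 85173758, 16 exons), whose coding sequence of 695 codons is the length of the neuronal form of amyloid precursor protein, held 93.0% ± 0.54 of the TPM of App. Camk2b-209 (21 exons) held 88.6% ± 2.4, Stmn2-201 67.7% ± 1.7, Snap25-201 64.1% ± 0.29 and Gnas-208 60.0% ± 1.9. Mef2c-212 held 44.0% ± 2.3, Ncam1-204 43.1% ± 3.3, Map2-204, of 1828 codons, 42.1% ± 2.2, Ptgds-202 38.2% ± 2.0 and Dclk1-201 28.8% ± 0.39.

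The 2 quantifications named a different leading transcript for 8 of the 43 genes. For Mbp the alignment-based tables led with Mbp-211, a form of 128 codons, at 48.0% ± 7.6, where the alignment-free tables gave it 13.4% ± 5.4 and led with Mbp-201 at 28.1% ± 1.9. Syn2-203 held 67.2% ± 7.0 in the former and 0.102% ± 0.026 in the latter, which led with Syn2-202, of the same 479 codons, at 55.7% ± 9.0. Ptgds-202 and Dclk1-201 were at 0% and 1.90% ± 0.91 in the latter, with Ptgds-201 (65.2%) and Dclk1-204 (33.9%) leading. The other genes were Ptbp2, Map4, Dnm1 and Aplp2. Between libraries, 40 of the 43 genes kept their leading transcript in the alignment-free tables, with Ptbp2 and Homer1 among the exceptions.

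Across genes the 2 libraries had a Pearson r of 0.985 and a Spearman rho of 0.986 for log2(TPM + 1) over 16284 genes at 1 TPM or more in either; genes are not independent replicates. They were not the same library deposited again, since counts differed beyond sampling noise, with a chi-square of 13.9 per degree of freedom over 16459 genes. The median per gene was 1.45, so that this mean was carried by the genes above the median. Sampling noise alone gives a median under 1, so the typical gene exceeded it too. The ERCC spike-ins, added in equal mixture, gave 4.24 over 35 spike-ins, with a median of 1.11, so that they also exceeded sampling noise. The common biological coefficient of variation by edgeR was 7.58% over 17577 genes, and 6.54% for nuclear protein-coding genes alone.

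**Figure D3:**
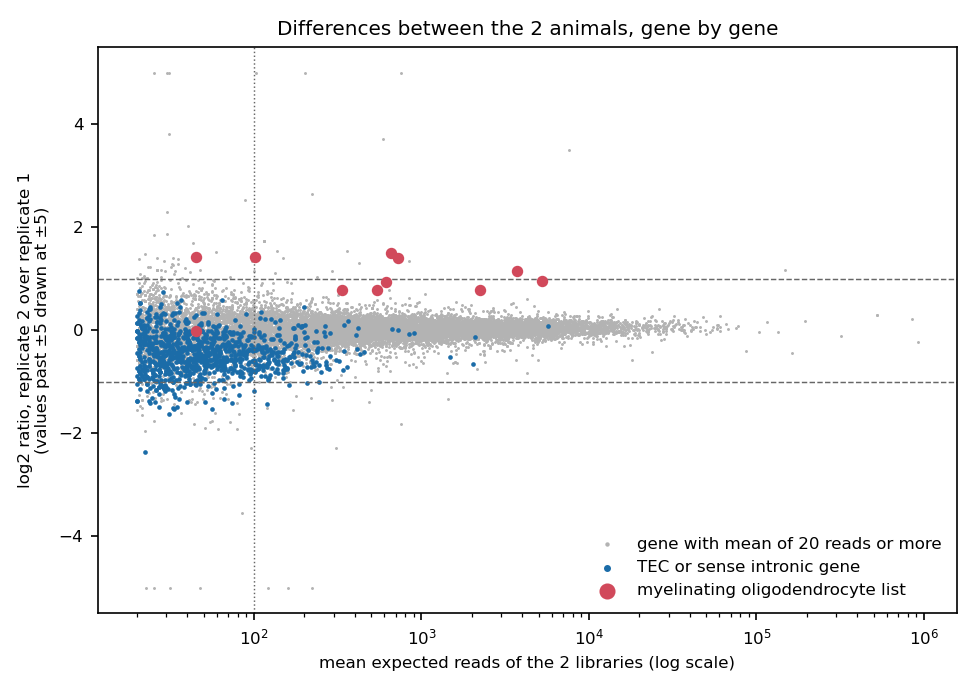
Log2 ratio of reads in replicate 2 over replicate 1 against mean expected reads (log axis) for 16459 genes, with dashed lines at 2-fold and a dotted line at 100 reads. Ratios past 5 are drawn at 5, myelin genes (large red points) lie above 0 except Aspa, and TEC or sense intronic genes (blue) lie mostly below.

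Few genes differed strongly between the animals, and 4 myelin genes were among those that did. Of 12689 genes with a mean of 100 expected reads or more, 24 were at least 2-fold higher in replicate 2 and 21 at least 2-fold lower, which compares 2 libraries and has no replicate check. With ratios of TPM the split was 26 higher and 41 lower. These ratios were not centred for this count, and their median over all genes was -0.11. The balance depended on the limits, with 65 higher and 153 lower at 1.5-fold, and 70 and 164 from 20 reads on. Of the 24 higher genes 4 were myelin genes, among them Mobp (343 and 975 reads, 2.81-fold), Mog (2.67-fold) and Mag (2.66-fold). Another 6 were pseudogenes and 5 were snRNA or snoRNA genes.

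The 10 largest ratios upward were mostly of genes with close copies, which are uncertain. The snRNA copy Gm24497 (at least 500-fold), the pseudogene Gm6565 (at least 132-fold) and Gm10163 (13.2-fold) were higher in replicate 2, and Gm14440 had 1.91 and 203 reads. Fam220a was 6.27-fold higher there, but 0.22 on the log2 scale in the alignment-free tables. The U3 snoRNA copies Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 each have 2 overlapping gene rows: the lower row was 3.31-fold higher, with the same values for all 4, and the more abundant row had a log2 ratio of 0.44. Lars2 (chromosome 9, 123366927 to 123462666), a mitochondrial leucyl-tRNA synthetase, had 1224 reads in replicate 1 and 13948 in replicate 2 (11.3-fold). The alignment-free tables gave 2882 and 48870, so the 2 quantifications disagree on its read number. Whether these reads come from the mRNA of this enzyme was not tested.

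In the other direction, the pseudogene Gm6361 (at least 149-fold), Gm20388 (at least 108-fold) and Gm14288 (at least 81.5-fold) were lower in replicate 2. The alignment-free tables kept Gm20388 but gave Gm14288 a log2 ratio of -0.30. The heparan sulfate enzyme Ndst4 was 4.91-fold lower (512 and 105 reads), the microtubule-severing gene Fign 2.93-fold, the desmosomal cadherin Dsc3 2.85-fold, the calcium sensor Hpcal1 2.62-fold and the cadherin Dchs2 2.56-fold, and all 5 kept a 2-fold difference in the alignment-free tables. The TEC gene Gm42843 was 2.69-fold lower. Zc3h11a, a symbol carried by 2 overlapping gene rows, was 3.56-fold lower in one row and 2.55-fold higher in the other, and the alignment-free tables turned both directions. Of the 24 higher genes the alignment-free tables kept 10 past 2-fold, lost 2 and gave 12 under 20 reads; of the 21 lower genes they kept 14, lost 6 and gave 1 under 20 reads.

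**Figure D4:**
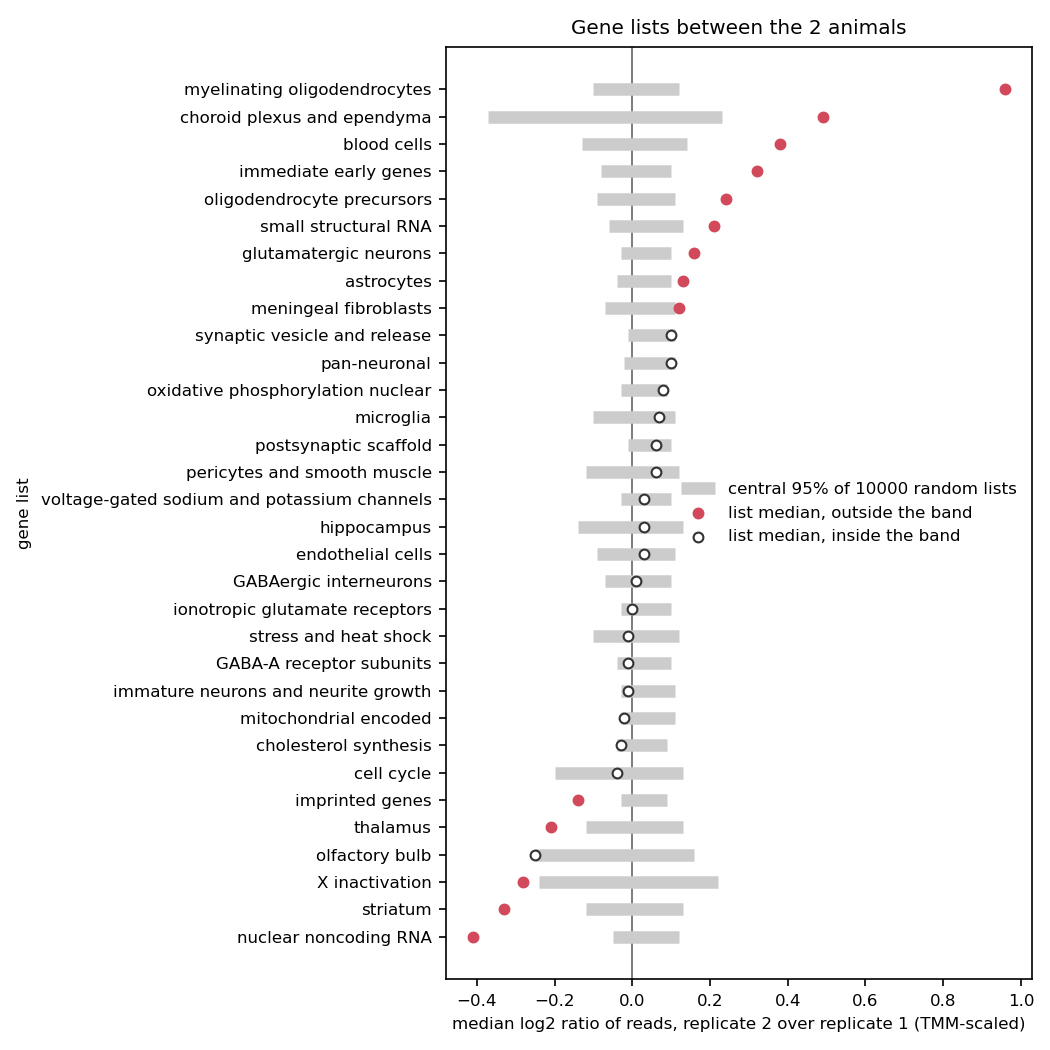
Median log2 ratio of reads in replicate 2 over replicate 1 for 32 gene lists (points), with the central 95% of the medians of 10000 random lists matched on size and expression (grey bars). Myelinating oligodendrocytes lie highest at 0.96 and nuclear noncoding RNA lowest at -0.41.

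List by list, 14 of 32 lists lay outside the central 95% of random lists, 9 higher and 5 lower in replicate 2, where 1.6 would do so for lists of unrelated genes; members of these lists vary together and some lists share members, so more can be reached without a specific difference. The myelin list had a median log2 ratio of 0.96 (SE 0.167), or 1.95-fold, with 10 of 11 measured members higher in replicate 2. Mbp (chromosome 18, 82475146 to 82585637) was at 0.96. Oligodendrocyte precursor genes were at 0.24 with 8 of 10 higher, and immediate early genes at 0.32 with all 14 higher, among them Egr1 at 0.39. The choroid plexus and ependyma list was at 0.49 with 5 of 6 higher, led by Ttr (2.63-fold), and the blood list at 0.38, with Hbb-bs at 0.35. Small structural RNAs (0.21), glutamatergic genes (0.16, 12 of 14 higher), astrocyte genes (0.13) and meningeal genes (0.12) were slightly higher. After removal of the trend with GC content and length the small structural list (0.07) and the meningeal list (0.08) lay inside the random band, as did the meningeal list with ratios of TPM (0.06).

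Nuclear noncoding RNAs were lower in replicate 2 with a median of -0.41 (SE 0.136) and 9 of 11 members lower, among them Malat1 at -0.44, Meg3 at -0.41 and Rmst, chosen after its values were seen, at -1. Gm26917, the member highest in TPM, went the other way at 0.22. Striatal genes were at -0.33 with 9 of 10 lower. The enkephalin gene Penk was at -0.96. The X inactivation list (-0.28), the thalamic list (-0.21, 5 of 9 lower) and the imprinted list (-0.14, 14 of 21 lower) were lower as well; the last shares Meg3, Rian and Kcnq1ot1 with the noncoding list. With ratios of TPM, whose median over all genes was -0.11, the thalamic list was at 0.01 relative to that median. The X inactivation list lay inside the band with these ratios (-0.25) and after removal of the trend with GC content and length (-0.23). The remaining 18 lists lay inside the band, from -0.25 for the olfactory bulb to 0.10 for the pan-neuronal and synaptic vesicle lists. The microglial list was at 0.07, the endothelial list at 0.03, the pericyte list at 0.06, GABAergic interneurons at 0.01, the cell cycle at -0.04 and cholesterol synthesis at -0.03. The Y-linked and interferon lists had fewer than 4 measured members.

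**Figure D5:**
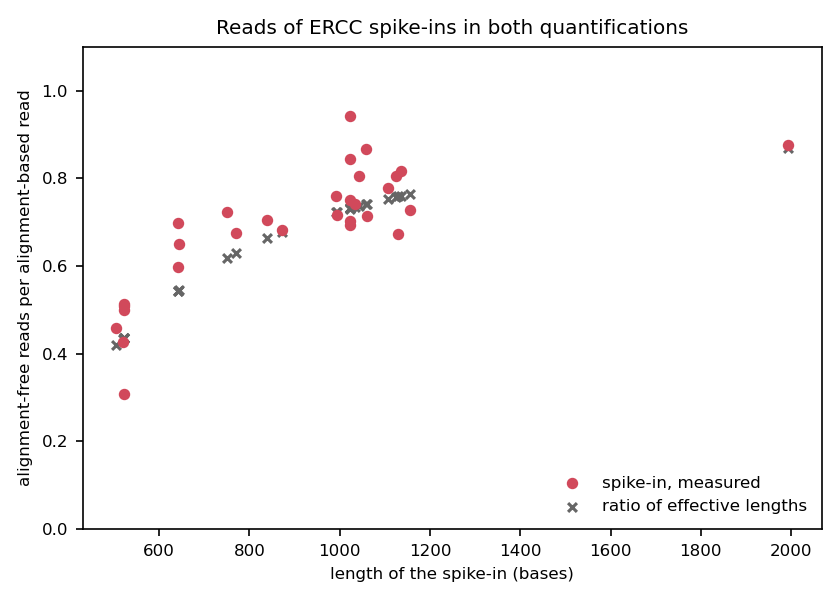
Alignment-free reads per alignment-based read (both libraries summed) for 30 ERCC spike-ins against their length in bases (points), with the ratio of the effective lengths of the 2 quantifications (crosses). The median is 0.479 for 6 spike-ins under 600 bases and 0.777 for 15 of 1000 bases or more.

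Between the 2 quantifications, short genes stood apart. Across genes at 1 TPM or more in either, Pearson r of log2(TPM + 1) was 0.876 ± 0.00082, with 3050 genes in replicate 1 and 2994 in replicate 2 over 2-fold apart. For genes of 1000 bases or more r was 0.968 ± 0.0029, and for genes under 350 bases 0.0447 ± 0.014. Of 170 genes under 350 bases at 10 TPM or more, 160 were under 0.1 TPM in the alignment-free tables. The 10 largest differences were all of short RNAs: Rn7sk, Rn7s1, Rn7s2, both rows of Rmrp, the snRNA copies Gm23444, Gm23472 and Gm24265, the mitochondrial gene mt-Atp8 and Rpph1. Rn7sk was at 42895 ± 1200 TPM in the alignment-based tables and listed at 0 in the alignment-free ones, and mt-Atp8, of 204 bases, at 1510 ± 28.5 TPM and at 0.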

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

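The tests on the oligodendrocyte lineage, on the share of neurons and both tests on short transcripts were chosen only after the result was seen. A further test, of the astrocyte gene Gfap as a sign of more white matter in the dissected piece, was dropped after its value was seen (log2 ratio -0.07), because its wording could not decide the question.

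Signals appeared in parts of the tables that no comparison used. The 26248 rows named by a number only held 6.88 reads in replicate 1, above the 3 reads that a count of 0 allows, and 1 read in replicate 2. The Y-linked genes, absent from female mice, held 164.7 reads in replicate 1 and 145.6 in replicate 2 of the alignment-free tables, against 3 and 3 in the alignment-based tables. Kdm5d held 92 and 91.1 of them and Uty 55.3 and 38.5. No explanation of these reads was tested.

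Myelin genes were higher in the library of replicate 2, with a median log2 ratio of 0.96. Removing the trend with GC content and length left 0.92, which argues against that trend as the whole cause. The smallest median over 4 scalings was 0.96. A change of scaling shifts all genes alike, the factors were nearly equal, and TPM ratios were centred on their median. The scaling test therefore could not decide the question. Precursor genes were at 0.24, under 0.5 of the myelin shift even with 2 standard errors added (SE 0.09). The difference between the lists was 0.73 (SE 0.19). These values argue narrowly against more cells of the whole lineage as the whole cause. The standard errors rest on genes that can vary together, not on animals. Precursor members ranged from -0.17 (Lhfpl3) to 0.55 (Enpp6), both chosen after their values were seen, with 8 of 10 higher. The median of that list therefore does not stand for every member. A difference between the animals in the timing of myelination, or in the dissected piece, stays open. The design names no group to test a biological explanation.

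Long nuclear noncoding RNAs were lower in replicate 2, with a median of -0.41. After the trend with GC content and length was removed they were at -0.38, and the pan-neuronal list was at 0.10, which argues against that trend and against fewer neurons as the whole cause. Within 2839 genes, transcripts with a retained intron were lower than protein-coding ones by a median of -0.287 (bootstrap interval -0.308 to -0.268), and by -0.26 in 1151 genes where both had near-equal GC content. A smaller share of unspliced nuclear RNA in that library is therefore a possible explanation. Whether it arose in the tissue or in the extraction was not tested. The bootstrap interval does not cover differences between animals. Genes of snRNA and snoRNA, without removal of the trend, went the other way, with medians of 0.27 and 0.41.

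Short RNAs such as Rn7sk were nearly absent from the alignment-free tables. All 16 genes under 350 bases at 10 TPM or more that share no word of 31 bases with another gene were under 0.1 alignment-free TPM (100%, interval 79.4% to 100%), which argues against reads shared between copies as the whole cause. Of the 154 genes with shared words, Rn7sk among them, 144 were also missing, and a part played by sharing stays open for these. The read ratios of 30 spike-ins followed the ratio of the effective lengths of the 2 quantifications, with a median of observed over predicted of 1.06 (0.706 to 1.29), so that reads near the 3' end left out of the alignment-free count are a possible explanation, but the shortest of these spike-ins has 505 bases and shorter RNAs were not tested. No biological explanation was tested.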

How the results depend on the processing

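The summary values compared here, with tolerances of 0.01 for r and 10% for the dispersion, were chosen after the data were seen, as were spike-in scaling and the removal of the trend with GC content and length. No paired analysis was possible because the design has only 1 group. Each replicate alone cannot give a value for comparisons of the replicates or for the pair count. The cause of the changes below was not tested.

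Genes detected stayed within 1.5 times the 14947 (10917 at 5 TPM to 17722 at 10 reads). The 706 long noncoding RNAs did not: they were 1116 at 0.5 TPM, 195 at 5 TPM, 1246 at 10 reads and 1411 in the alignment-free tables. Printed levels depend on the unit: of gene levels over all settings 292 moved past the spread of the replicates and 104 did not, and of list percentiles 88 moved and 184 did not. The pan-neuronal median of 346 TPM was 588 in the alignment-free tables and 696 rescaled to nuclear protein-coding genes, at percentiles of 99.35, 99.38 and 99.35. The small structural list went from percentile 99.94 to 17.88 in the alignment-free tables. All 24 pairs kept their sign under every setting. The protein-coding share was 49.7% of TPM, but 83.13% of reads and 79.54% of alignment-free TPM. Replicate r was 0.985, with 0.9573 at pseudocount 0.1 and 0.9953 for scaled counts. The dispersion was 7.58%, and 6.544% for nuclear protein-coding genes. The 45 genes past 2-fold (24 higher, 21 lower) became 218 at 1.5-fold (65 and 153) and 234 from 20 reads on (70 and 164). With TPM ratios, not centred for this count, 26 were higher and 41 lower. Zc3h11a, lower in 1 of its 2 gene rows, was reversed by alignment-free counts (log2 ratio 1.25). Between quantifications r was 0.876, with 0.6009 per transcript and 0.693 from 10 TPM on. The share of the leading transcript moved for 37 isoform genes in the alignment-free tables and stayed for 6; Stmn2-201 went from 67.7% to 99.6%.

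Of 32 lists 14 lay outside the random band, 13 with TPM ratios, 14 with DESeq2 factors, 14 with spike-in scaling and 16 after the removal of the trend. DESeq2 factors and spike-in scaling shift all genes alike, so they cannot change the place of a list among random lists. Their equal counts are therefore no check. With TPM ratios the thalamic list was reversed to 0.01; the meningeal and X inactivation lists also left, and the synaptic vesicle and ionotropic glutamate receptor lists entered. After the removal of the trend the meningeal, small structural and X inactivation lists left, and the GABAergic, pan-neuronal, immature neuron, ionotropic glutamate receptor and mitochondrial lists entered. Depth limits genes near 0.16 TPM per kb.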

Other observations

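The mitochondrial gene mt-Co3 and its chromosome 1 copy Gm28437, chosen after their values were seen, held 67914 reads together in replicate 1 and 67531 in replicate 2, while the share of mt-Co3 was 31.6% and 21.7%. For mt-Atp6 and Gm10925 the share of mt-Atp6 was 31.3% and 32.4%.

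Among gene classes, 150 of 170 TEC genes and 15 of 17 sense intronic genes with a mean of 100 reads or more were lower in replicate 2, with median log2 ratios of -0.47 and -0.50, and snRNA and snoRNA genes had medians of 0.27 and 0.41. Over 16448 genes the ratio of replicate 2 over replicate 1 had a Spearman rho of 0.381 with GC content and of -0.081 with length. Gm42418, chosen after its values were seen among the differing genes, was 2.24-fold higher in replicate 2. The origin of its reads was not tested.

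Over all 1570 genes of the Y chromosome alignment gave 74.12 and 45.23 reads, and the alignment-free quantification gave 3193.8 and 3454.4. Of these genes Gm47283 (chromosome Y, 90784738 to 90816464), chosen after its values were seen, was at 281.9 ± 57.6 TPM in the alignment-free tables. It was at 0 TPM in the alignment-based ones. Whether the reads of this total are specific to the Y chromosome was not tested.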
